A study of Rattus norvegicus with 12 samples.

How the data were processed

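Samples were assigned to the high Fe and low Fe groups from their titles. The titles number them as group 1 to 3, and these numbers are called replicates here. Only the titles of 230B samples name the array type, and the platform gives it for the others. The groups have 3 samples each on the Affymetrix rat arrays 230A and 230B. The labels do not say that the samples came from separate animals, so p-values measure only the spread between these samples, which may be technical. No arrays held identical values, and correlations between arrays ran from 0.943 to 0.977 on 230A and from 0.844 to 0.930 on 230B.

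The tables deposited by the authors hold 1 intensity per probe set and array, a linear signal that is never negative. The software that made the values is not given in the sources used here. From the values, each array had been scaled: the mean after leaving out 2% of probe sets at each end was 500.1 on every 230A array and 500.2 on every 230B array. This scaling sets the arrays of a type equal on average, so a change shared by most genes cannot show. It also sets the mostly dimmer 230B probe sets to the same mean, and the 100 probe sets on both types were 3.68 times as bright on 230B at the median. Signals are therefore compared within a type only. Medians of arrays differed little (154 to 176 on 230A, 259.5 to 303 on 230B), so no further normalization was applied. Deviations from group means of arrays with the same number correlated below 0 on both types, which gave no sign of pairing, and no block was used. Pairing is not excluded, since high Fe and low Fe samples with the same number fell in opposite sets by RNA quality (below).

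Gene names come from the platform annotation. Of 15866 probe sets on 230A, after 57 controls were left out, 12783 had 1 symbol, 312 several and 2771 none. Of 15276 on 230B, after 57 controls, 7564 had 1, 100 several and 7612 none. Through their Entrez identifiers, 12748 and 7524 of the 1-symbol probe sets matched the RefSeq gene table of assembly GRCr8, which was used for names only. Probe sets with several symbols, which include near-identical copies such as ferritins and globins, were tested and are not named.

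Values were transformed as log2(signal + 16), with a pseudocount of 16, and the 40% of probe sets with the lowest mean over the 6 arrays of a type were left out, which left 9519 on 230A (7051 named genes) and 9165 on 230B (4059 named genes). The filter boundary lay at a signal of 106 on 230A and 182.9 on 230B. Low Fe was compared with high Fe in limma 3.58.1 (R 4.3.3) with lmFit and eBayes with a mean-variance trend, each array type on its own, with Benjamini-Hochberg adjustment over the probe sets of the type and a threshold of adjusted p 0.05. Log2 differences and folds are on the log2(signal + 16) scale, which understates changes of dim genes. Means and SDs are of the linear signals. Where a gene had several probe sets, the one with the highest mean stands for it.

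Gene lists, 30 in all, cover iron, heme, copper and zinc, hypoxia, metabolism, absorption, proliferation, stress, inflammation, cell types of the gut wall and neighbouring gut regions. Lists with at least 5 tested genes were tested with camera of limma at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists of a type, and again with an estimated correlation and with fry. The groups, the test, the filter, the lists, the alternatives and the rule for named genes were fixed before the data were examined.

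The rule named, per array type, the 12 genes (230A) or 6 genes (230B) with the largest rise and as many with the largest fall among those past the threshold without overlap between the groups. Where fewer passed, the passing ones were taken and then those with the smallest unadjusted p in that direction, said not to pass. The rule also takes the iron handling genes, and up to 4 members of every other list with the smallest unadjusted p. For lists that did not pass, only some of these members are given here, a narrowing made after the data were seen. A few list members outside the rule, such as Ldha and Eno1, are given as examples and were chosen after their values were seen.

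The alternatives were other pseudocounts, filters and scalings, eBayes without a trend or robust, the replicate number as a block, each array left out in turn, the mean of all probe sets of a gene, the other array type and a threshold of 0.1. Scaling to the hybridization controls, a pseudocount of 64 and RNA quality as a block were added after the data were seen. The steps were tested on simulated data with 200 changed probe sets in each of 5 draws. The draws took the real means and random spreads around the smoothed real ones, with independent noise for each probe set. They lacked the correlation between genes and the RNA quality sets of the real data. With 200 changed probe sets the adjusted threshold is also easier to pass than in the real data, where 9 passed on 230A. Real recovery may thus be lower. On 230A (9519 probe sets), 75.8% of 2-fold and 83.6% of 4-fold changes were recovered, and 3.9% of calls were false. On 230B (9165 probe sets) the values were 50.8%, 74.6% and 5.7%. A list shifted by a log2 of 0.5, the fat absorption list, was called in 5 of 5 draws on either type.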

Results

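Gene expression was measured in scrapings of the jejunal mucosa, the lining of the middle part of the small intestine, from rats of a high Fe group and a low Fe group. The labels give a week number of 12 for all samples and name iron deficiency and anemia as keywords. Each group had 3 samples, and each sample was run on a pair of Affymetrix arrays, 230A and 230B, which carry different probe sets, for 12 arrays in all. Median signals ran from 154 to 176 on 230A and from 259.5 to 303 on 230B, and the number of arrays limits the precision of every value below. The 100 probe sets that both types carry matched the samples across them: each of the 6 samples on 230A resembled most the 230B array with the same group and number.

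Of the tested genes of the iron handling list, 4 had more transcript in low Fe mucosa, Cybrd1, Tfrc, Slc11a2 and Hmox1. Cybrd1, the ferric reductase of the intestinal brush border, rose from a signal of 303 ± 71.4 in high Fe to 4981 ± 1865 in low Fe (mean ± SD, n = 3 each), 15.1-fold. Tfrc, the transferrin receptor, rose from 602 ± 154 to 4114 ± 971, or 6.70-fold. Slc11a2, the divalent metal transporter that carries ferrous iron across the apical membrane, rose from 2815 ± 560 to 12758 ± 837, or 4.56-fold. Hmox1, the heme oxygenase that releases iron from heme, rose from 582 ± 115 to 1449 ± 67.7, or 2.48-fold.

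**Figure D1:**
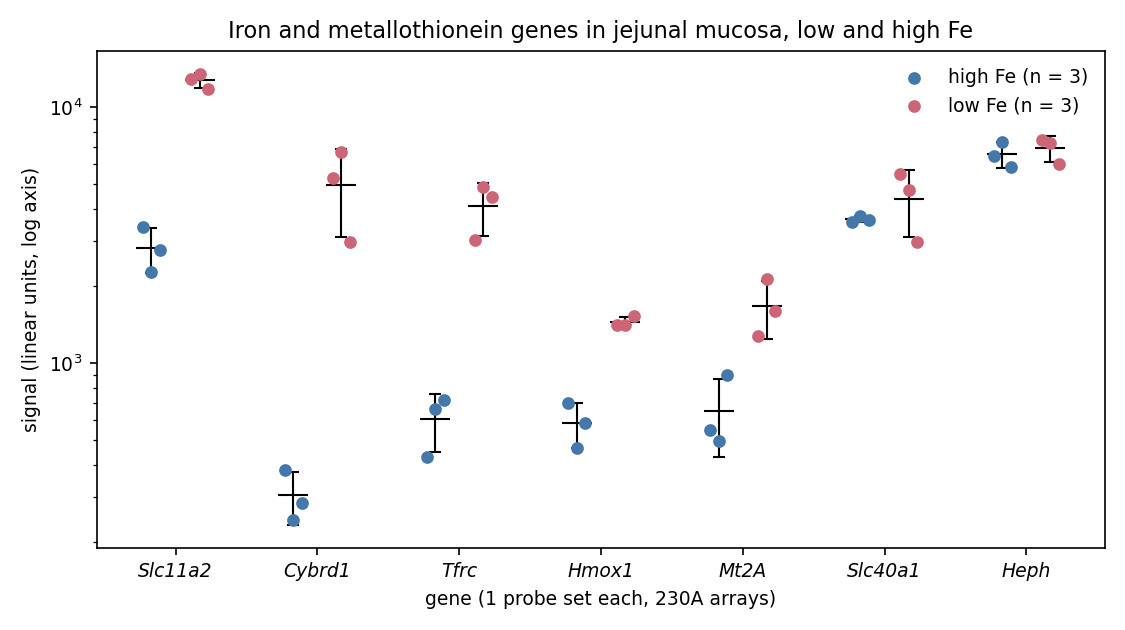
Signal of 7 genes on each 230A array (log axis), with high Fe arrays in blue, low Fe arrays in red, and black bars for the mean and SD of 3 arrays. For Slc11a2, Cybrd1, Tfrc, Hmox1 and Mt2A every low Fe array lies above every high Fe array, and for Slc40a1 and Heph the groups overlap.

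The log2 differences, low Fe minus high Fe, were 3.91 ± 0.28 (SE) for Cybrd1, 2.74 ± 0.23 for Tfrc, 2.19 ± 0.15 for Slc11a2 and 1.31 ± 0.16 for Hmox1. Their limma adjusted p-values were 0.000892, 0.00216, 0.000892 and 0.0251. Less bright second probe sets gave 1.73 ± 0.26 for Slc11a2 (adjusted p = 0.0806) and 1.67 ± 0.41 for Tfrc (adjusted p = 0.488), which did not pass. Slc40a1, the basolateral iron exporter ferroportin, had a log2 difference of 0.22 ± 0.21 (adjusted p = 0.857), with 0.37 ± 0.15 (adjusted p = 0.720) and -0.03 ± 0.24 for its less bright probe sets, and Heph, the ferroxidase hephaestin, one of 0.07 ± 0.14 (adjusted p = 0.921). Without 1 array these ran from 0.04 to 0.48 for Slc40a1 and from -0.0013 to 0.17 for Heph. Atp7a, the copper-exporting ATPase, measured on 230B, went from 2468 ± 229 to 6615 ± 1438, a log2 difference of 1.40 ± 0.19 that did not pass (adjusted p = 0.139). A less bright 230B probe set of Atp7a gave -0.04 ± 0.19. Mt2A, a metallothionein that binds zinc and copper, went from 648 ± 221 to 1667 ± 426, a log2 difference of 1.36 ± 0.25 (adjusted p = 0.184). The fixed genes Fth1, Ftl1 and Mt1a had no tested probe set assigned to them alone.

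Of the 23 tested genes of the iron handling list, taken over both array types, 4 rose and 19 did not pass, with log2 differences from -0.94 to 0.49. Bmp6, a ligand that induces hepcidin, was at the low end of that range (-1.44 without low Fe replicate 1) and Slc25a37, the mitochondrial iron importer mitoferrin, at the high end (0.14 without high Fe replicate 1). Slc46a1, a folate transporter that can also carry heme, gave -0.41 ± 0.20 (-0.63 without low Fe replicate 1 and -0.21 without low Fe replicate 2). Slc39a14 and Slc39a8, metal transporters that can carry iron, gave 0.07 and -0.03, and ran from -0.02 to 0.16 and from -0.08 to 0.02 without 1 array. Epas1, a hypoxia-inducible factor subunit, gave 0.43 ± 0.15 (-0.53 ± 0.35 for a less bright probe set), and Steap1, a metalloreductase family member, gave 0.44 ± 0.18 on 230B. On 230A the list passed as higher (19 genes, median log2 difference 0.06, camera adjusted p = 0.000198, and 0.129 with an estimated correlation). With 11 genes above 0, 8 below and a mean of 0.55, the call reflects a few large rises and not a shift of the whole list. Its 4 genes past the threshold over all probe sets were also the 4 past it when adjusted over the list alone.

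The 3 iron uptake genes Slc11a2, Cybrd1 and Tfrc were also compared among samples alike in 1 sign of RNA quality. A 5'/3' signal ratio of GAPDH control probe sets, a sign of RNA and target quality, was lower in high Fe replicate 1 and low Fe replicates 2 and 3 (0.794 to 0.811 on 230A) than in the other arrays (0.876 to 0.922). By the same ratio of beta-actin the lower set was not alike. That ratio was 0.054 in low Fe replicate 3, against 0.62 in high Fe replicate 1 and 0.591 in low Fe replicate 2. Within the lower set, 1 high Fe and 2 low Fe arrays with no test, the log2 differences were 1.89 for Slc11a2, 3.49 for Cybrd1 and 3.40 for Tfrc. Within the higher set, 2 high Fe and 1 low Fe array, they were 2.36, 4.25 and 2.11.

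Over the whole 230A type, 9 of 9519 tested probe sets passed adjusted p 0.05, with 8 higher and 1 lower in low Fe. Beside the iron genes, P4ha1, the catalytic subunit of collagen prolyl hydroxylase and a target of hypoxia-inducible factors, rose by 1.19 ± 0.16 on the log2 scale, from 172 ± 15.6 to 415 ± 51.5 (adjusted p = 0.0422). Ugt2b35, a UDP-glucuronosyltransferase of steroid and drug conjugation, fell by 1.26 ± 0.13, from 1586 ± 115 to 656 ± 57.8 (adjusted p = 0.00859). A probe set annotated to Commd7, chosen here after its values were seen, had a log2 difference of 2.50 ± 0.28 (adjusted p = 0.0153). Its high Fe mean of 74.5 lay under the filter boundary of 106. The brighter Commd7 probe set gave 0.24 ± 0.16 and the one on 230B 0.13 ± 0.19. The first did not pass without high Fe replicate 2 (0.0606), low Fe replicate 2 (0.0559) or low Fe replicate 3 (0.0626). The other 2 probe sets have no gene assigned here. Of these, 1 rose from 89.8 ± 8.8 to 1968 ± 678 (adjusted p = 0.00056), and the other from 86.9 ± 6.2 to 355 ± 31.1 (adjusted p = 0.00216).

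Several genes stood apart without overlap between the groups and did not pass the threshold. Among those higher in low Fe were Gpr6, an orphan receptor (1.75 ± 0.25, adjusted p = 0.0548), Egln3, a prolyl hydroxylase that marks hypoxia-inducible factors for degradation (0.99 ± 0.14, adjusted p = 0.0548), and Mpzl2, an epithelial adhesion protein (1.12 ± 0.17, adjusted p = 0.0847). Gpr6 was dim: its mean signal was 56.6 in high Fe, under the filter boundary of 106, and 237 in low Fe. Pmp22, a membrane protein of myelin and epithelia, gave 1.23 (0.45 ± 0.35 for a less bright probe set). Pcna, the sliding clamp of DNA replication, gave 0.99, Ctla2a 0.80 and Dcaf17 0.77. Among those lower were Ugt2b7 (-1.29 ± 0.18, adjusted p = 0.0541) and Ugt2b15 (-0.97), which belong to the same enzyme family as Ugt2b35. Sgk1, a kinase of sodium transport, gave -1.39, Slc34a2, a sodium-phosphate cotransporter, -0.95, Hif1a, the hypoxia-inducible factor subunit, -0.87, and Fbp1, a gluconeogenic enzyme, -0.58. Gpr6, Egln3, Mpzl2, Ugt2b7, Pmp22, Hif1a and Slc34a2 passed under at least 1 alternative, Hif1a and Slc34a2 only without low Fe replicate 1. Rbp7 gave -0.88, Mtarc1 -0.78, Mfge8 -0.67, Ythdf2 -0.65 (-0.25 ± 0.19 for a less bright probe set) and Srebf1 -0.57.

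The count of 9 rested on few samples. It was 21 (12 higher, 9 lower) without low Fe replicate 1 and 5 without low Fe replicate 2. It was 33 (25 higher, 8 lower) after scaling to the hybridization controls, which moved the median log2 difference of all probe sets from -0.015 to 0.342. That scaling moved high Fe replicate 2 most: its control mean (log2) was 10.265, against 9.226 to 9.517 on the other 230A arrays. The 230A probe sets that passed under it all had log2 differences at least 1.3786 from 0. Slc11a2, Cybrd1 and Tfrc passed without any 1 array, with a highest adjusted p of 0.0276. Hmox1 did not pass without high Fe replicate 2 (0.0606), high Fe replicate 3 (0.118), low Fe replicate 2 (0.188) or low Fe replicate 3 (0.136). P4ha1 passed only without low Fe replicate 1, with adjusted p from 0.109 to 0.308 without each of the other arrays. Ugt2b35 did not pass without high Fe replicate 3 (0.0825) or low Fe replicate 2 (0.0644), nor after scaling to the hybridization controls, where its log2 difference was -0.89 (adjusted p = 0.695). With no filter on dim probe sets, Hmox1 (0.0737) and P4ha1 (0.125) did not pass. At an unadjusted p under 0.05 there were 636 probe sets, 302 higher and 334 lower, against 476 by chance. The groups did not overlap for 11.8% of probe sets, where chance gives 10%.

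Targets of hypoxia-inducible factors rose as a list in low Fe (29 genes, median log2 difference 0.24, camera adjusted p = 8.06e-07), and the adjusted p was 0.0801 with an estimated correlation. Over all probe sets 1 member, P4ha1, passed, and 7 passed when adjusted over the list alone, all higher. These were P4ha1, Egln3, Slc2a1, a glucose transporter (0.62 ± 0.14), Ero1a, an endoplasmic reticulum oxidase (0.66 ± 0.15), Mxi1, a Myc antagonist (0.48 ± 0.12), Bnip3, a mitophagy receptor (0.82 ± 0.23), and Slc16a3, a lactate exporter (0.47 ± 0.13). Less bright probe sets gave 0.06 ± 0.26 for Ero1a and -0.36 ± 0.58 for Mxi1. Of 3 further members, chosen after their values were seen, the glycolytic enzymes Ldha, Eno1 and Pgk1 gave -0.07 ± 0.17, -0.06 ± 0.14 and 0.26 ± 0.12. Without 1 array Ldha ran from -0.23 to 0.09 and Eno1 from -0.15 to 0.06.

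**Figure D2:**
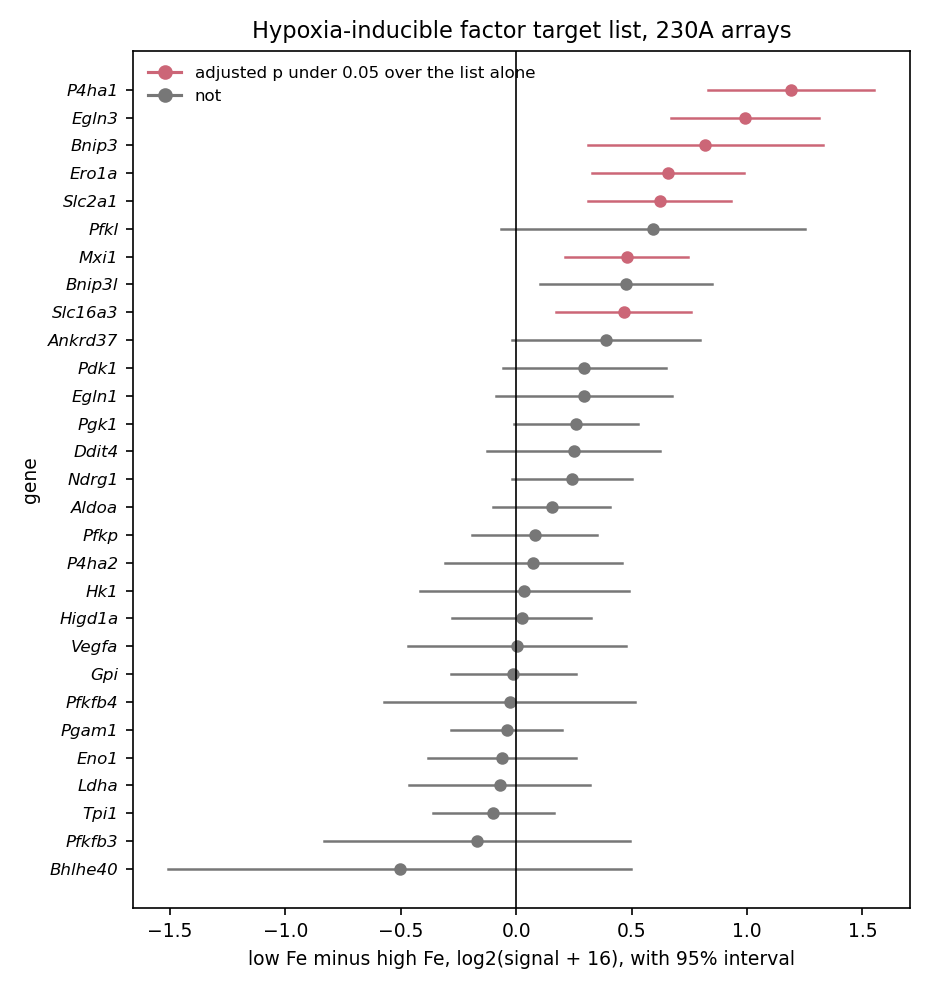
Log2 difference, low Fe minus high Fe, with its 95% interval, for the 29 tested genes of the hypoxia-inducible factor target list on 230A; red marks the 7 genes past adjusted p 0.05 over the list alone. P4ha1 lies highest at 1.19, and 8 genes lie below 0.

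Of the 30 lists fixed beforehand, 24 had at least 5 tested genes on 230A, and 9 passed adjusted p 0.05, 6 higher and 3 lower in low Fe. None passed with an estimated correlation, for which the smallest adjusted p was 0.0801 and which also rests on the 4 residual degrees of freedom. The estimated correlation was -0.02 for hypoxia targets, -0.0002 for iron handling, 0.02 for interferon, 0.08 for heat shock, 0.10 for vitamin and mineral, 0.13 for fat absorption, 0.29 for smooth muscle, 0.35 for brush border and 0.52 for cell cycle genes. The test compares a list with all other genes, so a direction is relative to these. At the preset correlation, other splits of the 6 samples called 6, 6, 5, 1, 3, 4, 0, 7 and 4 lists. These splits mix the iron groups, so a pass at that setting is weak evidence for any 1 list. By fry, which asks whether the genes of a list move one way on balance, 2 passed, the hypoxia targets (adjusted p = 0.0171) and iron handling (adjusted p = 0.0109).

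Fat absorption and lipid genes fell as a list (31 genes, median -0.16, adjusted p = 2.03e-05; adjusted p = 0.273 with an estimated correlation). The members with the smallest p were Srebf1, a regulator of lipid synthesis (-0.57 ± 0.14), Angptl4, an inhibitor of lipoprotein lipase (-0.55 ± 0.20), Acadm, a fatty acid dehydrogenase (-0.33 ± 0.14), and Pdk4, a kinase that restrains glucose oxidation (-0.83 ± 0.35). None of the 31 passed over all probe sets or adjusted over the list alone, and Pdk4 gave -0.47 without high Fe replicate 2. Acadm gave 0.04 after scaling to the hybridization controls, under the median of 0.36 over all tested genes. Vitamin and mineral absorption genes fell as a list (22 genes, median -0.19, adjusted p = 0.00646; adjusted p = 0.430 with an estimated correlation), with 0 past over all probe sets or adjusted over the list alone. It held the calcium genes Trpv6, an apical channel (-1.08 ± 0.43), S100g, a cytosolic calcium carrier (-0.45 ± 0.18), and Atp2b1, a basolateral pump (-0.63 ± 0.24 on 230A, and 0.54 ± 0.32, 0.16 ± 0.42 and -0.70 ± 0.27 from the brightest to the dimmest of its 3 probe sets on 230B), and Slc26a3, a chloride exchanger (-0.48 ± 0.16). Trpv6 gave -0.48 without low Fe replicate 3, and S100g gave -0.25 without high Fe replicate 2. Brush border and digestive genes also fell as a list (26 genes, median -0.09, adjusted p = 0.0256; adjusted p = 0.720 with an estimated correlation), with 1 gene, Slc34a2, past when adjusted over the list alone and 0 over all. Espn, an actin bundler of microvilli, gave -0.42 ± 0.13, and Slc2a5, the fructose transporter, -0.68 ± 0.25 (-0.44 without high Fe replicate 2). Slc1a1, a glutamate transporter, gave 0.75 ± 0.24, and 0.17 ± 0.21 for a less bright probe set.

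The brush border list and the vitamin and mineral list did not pass with the GAPDH ratio sets as a block (adjusted p = 0.520 and 0.0698), and the fat absorption list passed. Without high Fe replicate 2 and without low Fe replicate 2, the brush border list gave 0.692 and 0.216 and the vitamin and mineral list 0.115 and 0.0580. The brush border list also gave 0.237 without low Fe replicate 3, 0.888 after scaling to the hybridization controls, and 0.0564 to 0.0858 with no trend, no filter, a common median or quantile normalization. After scaling to the hybridization controls the medians of the fat, vitamin and mineral, and brush border lists were 0.21, 0.18 and 0.28, all under the median of 0.36 over all tested genes.

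Heat shock and immediate early genes rose as a list (19 genes, median 0.30, adjusted p = 3.55e-05; adjusted p = 0.253 with an estimated correlation), with 4 past when adjusted over the list alone and 0 over all. The 4 were Fosb (1.33 ± 0.31), Egr1 (0.64 ± 0.19) and Ier3 (0.45 ± 0.12), which respond within minutes to stimulation, and the chaperone Hspa1a (0.55 ± 0.17). Cell cycle genes rose as a list (24 genes, median 0.25, adjusted p = 0.00192; adjusted p = 0.720 with an estimated correlation), with Pcna past when adjusted over the list alone and 0 genes over all. The proliferation marker Mki67 gave 0.76 ± 0.26, the cyclin-dependent kinase Cdk4 0.44 ± 0.20 (0.28 without low Fe replicate 2) and the mitotic kinase Aurkb -0.45 ± 0.20. The cell cycle list did not pass without high Fe replicate 1 (0.273) or low Fe replicate 2 (0.216). Interferon and inflammation genes rose as a list (22 genes, median 0.19, adjusted p = 0.0256; adjusted p = 0.273 with an estimated correlation), with 0 past over all or adjusted over the list alone. Irf7, an interferon regulatory factor (0.41 ± 0.14), Psmb9, an immunoproteasome subunit (0.43 ± 0.15), and Oas1a, an antiviral enzyme (0.46 ± 0.18), lay above 0, and Reg3g, an antibacterial lectin, gave -0.55 ± 0.22. That list did not pass without high Fe replicate 1 (0.0984), high Fe replicate 2 (0.0675) or low Fe replicate 1 (0.359), nor with no filter (0.112) or with the lowest 60% left out (0.102).

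Smooth muscle markers rose as a list beside these groups (7 genes, median 0.43, adjusted p = 0.000259; adjusted p = 0.273 with an estimated correlation), with 2 past when adjusted over the list alone and 0 over all. All 7 lay above 0, among them Smtn, smoothelin (1.11 ± 0.29), Mylk, myosin light chain kinase (0.43 ± 0.13), Des, desmin (0.59 ± 0.22), and Acta2, smooth muscle actin (0.29 ± 0.19, with 0.49 without low Fe replicate 1 and 0.14 without low Fe replicate 3). Smtn and Des were dim, with mean signals of 79.4 and 96.6 in high Fe, under the filter boundary of 106. A further sign of RNA quality differed: the 5'/3' ratio of beta-actin control probe sets was 0.054 in low Fe replicate 3, against 0.591 to 0.836 on the other 230A arrays.

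**Figure D3:**
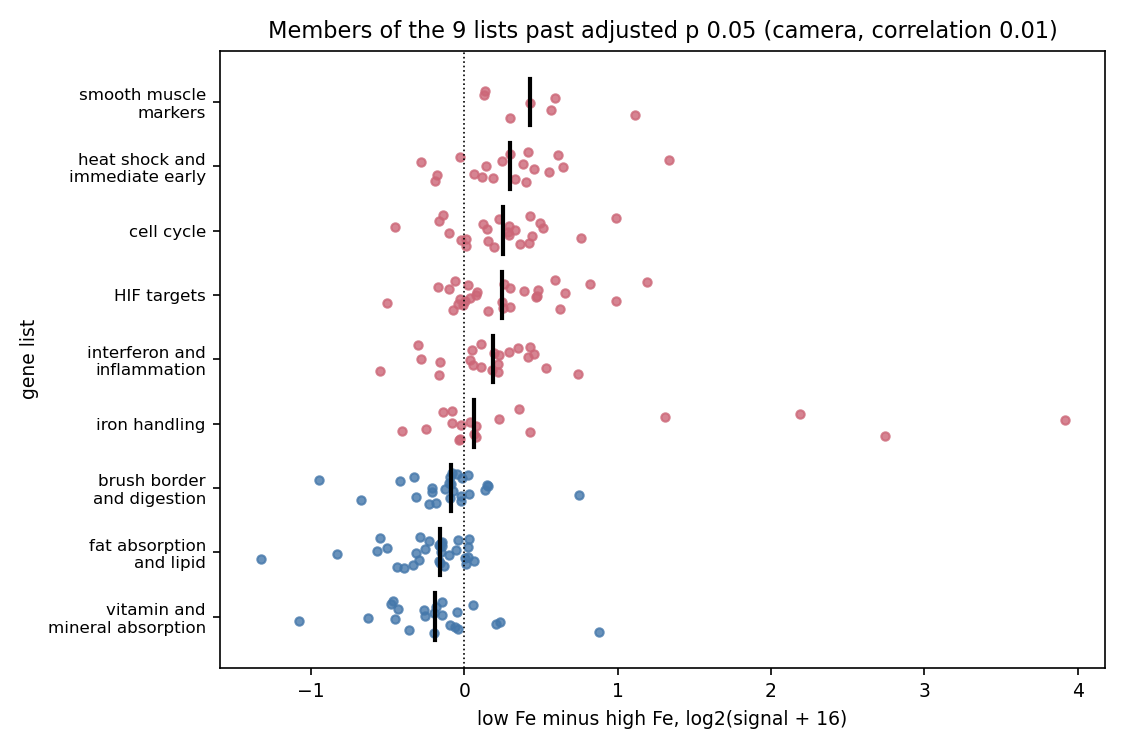
Log2 difference, low Fe minus high Fe, of each tested gene of the 9 lists past adjusted p 0.05 on 230A with the preset correlation, red for lists higher and blue for lists lower in low Fe; black bars mark list medians. The medians run from -0.19 for vitamin and mineral absorption to 0.43 for smooth muscle markers, and the iron handling list holds 4 genes above 1 while its median is 0.06.

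The other 15 tested lists did not pass. Among cell type markers, the adjusted p was 0.180 for myeloid cells, 0.379 for stroma and endothelium, 0.409 for goblet cells, 0.495 for red blood cells, 0.820 for T and natural killer cells, 0.820 for enteroendocrine cells and 0.907 for tuft cells. Among pathways it was 0.0920 for stem and crypt genes, 0.124 for heme metabolism, 0.656 for cholesterol synthesis, 0.656 for endoplasmic reticulum stress, 0.820 for oxidative phosphorylation and iron-sulfur proteins, 0.820 for copper, zinc and metallothioneins, 0.820 for antioxidant genes and 0.822 for circadian genes. Of these 15, the myeloid list passed, higher in low Fe, without high Fe replicate 3 (0.0203) or low Fe replicate 3 (0.0263), with the mean of all probe sets (0.0425), with the GAPDH ratio sets as a block (0.0299) and after scaling to the hybridization controls (0.00758). On 230A its median was 0.12 and its mean 0.23, with 10 of 13 genes above 0. Its 3 tested genes on 230B all lay below 0. The stem and crypt list passed, also higher, without high Fe replicate 3 (0.00352) or low Fe replicate 1 (0.0246) and after scaling to the hybridization controls (0.00259), and goblet cell markers passed, lower, without high Fe replicate 1 (0.0138). Adjusted over the list alone, Hmox1 and Alas1, the first enzyme of heme synthesis (0.61 ± 0.13), passed in the heme list, Mt2A in the copper and zinc list and Gpx2, a glutathione peroxidase (0.88 ± 0.17), in the antioxidant list, and no gene passed in the others. Over all probe sets Hmox1 alone of these passed. The antioxidant genes Gclm (-0.52 ± 0.14) and Gclc (0.43 ± 0.15, and 0.10 ± 0.24 for a less bright probe set), subunits of one enzyme, lay on opposite sides of 0. Hbb, the beta globin, gave -0.54 ± 0.19, Slc39a4, the zinc importer, -0.40 ± 0.12, Cd8a, a T cell marker, -0.66 ± 0.19, and Cox4i1, a respiratory chain subunit, -0.24 ± 0.12 (-0.15 without high Fe replicate 3). For red blood cell, circadian, oxidative phosphorylation and tuft cell lists the median lay above 0 (0.0069, 0.03, 0.0026 and 0.02) while the mean and the test pointed down, and for copper and zinc the mean (0.01) lay above 0 while the median and the test pointed down. Of the 6 lists with fewer than 5 tested genes, medians were -0.19 for mast cells, 0.07 for pancreas, 0.43 for Paneth cells, -0.07 for duodenal and -0.13 for ileal genes, and no B or plasma cell gene was tested. Single arrays moved these medians: mast cells gave 0.05 without low Fe replicate 1, pancreas -0.05 without low Fe replicate 2 and Paneth cells 0.11 without high Fe replicate 1.

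On the 230B arrays no gene passed, and the genes with the smallest p in each direction are given here. Cd69, an early activation marker of lymphocytes, had a log2 difference of 1.35 ± 0.18, Thoc2, a subunit of an mRNA export complex, 1.26 ± 0.17 (0.26 ± 0.16 for another probe set), and Atp7a, above, was the third, all with adjusted p = 0.139. Zfp503 gave 1.18, Tshz1 1.08 and Itga6, an epithelial integrin, 1.01 on 230B and -0.34 on 230A (0.31 and 0.07 for less bright probe sets). On the lower side Lhfpl6 gave -1.28, Pdk4 -1.21, Plch1 -1.15, Fnbp4 -0.97 on 230B and 0.24 on 230A, RT1-Ba, a class II histocompatibility chain, -0.87 on 230B with -0.42 (-0.76 to -0.24 without 1 array) and 0.42 from its 230A probe sets, and Fam221b -0.79. Of 9165 probe sets tested with limma, the only tool run, 0 passed adjusted p 0.05, and 932 had an unadjusted p under 0.05 (453 higher, 479 lower; 458 by chance). The groups did not overlap for 17.4% of probe sets, where chance gives 10%. The residual SD was 0.288 at the median probe set, against 0.204 on 230A. In simulated data without correlation between genes, 50.8% of 2-fold changes were recovered on 230B (9165 probe sets), against 75.8% on 230A (9519 probe sets). These draws held 200 changed probe sets each, which eases the adjusted threshold, so real recovery may be lower.

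The 6 lists with at least 5 genes on 230B did not pass, with adjusted p = 0.176 for fat absorption and lipid, 0.407 for circadian genes, 0.407 for copper, zinc and metallothioneins, and 0.580 for iron handling, oxidative phosphorylation and heme metabolism alike. The fat list passed, lower in low Fe, without high Fe replicate 3 (0.0241) and with quantile normalization (0.0116), and with no filter the interferon list reached 5 genes and passed, higher (0.00742). With an estimated correlation 0 passed as well. In simulated data the fat absorption list, shifted by a log2 of 0.5, was called in 5 of 5 draws on 230B. The simulated genes were independent, so this does not show that such a shift would be called among correlated genes. Adjusted over the list alone, Pdk4 passed in the fat list, Atp7a in the copper and zinc list, and, in lists too small for the list test, Gzma, a granzyme (0.89 ± 0.18), and RT1-Ba. For iron handling the mean (-0.0024) lay below 0 while the median (0.14) and the test pointed up. Over the 1308 genes tested on both types, log2 differences had a Pearson correlation of 0.087 across genes, which are not independent replicates. Of 78 of these with an unadjusted p under 0.05 on 230A, 44 (56.4%) had the same sign on 230B.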

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

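Scaling to the hybridization controls, a pseudocount of 64 and the block by RNA quality were chosen after the data were seen. Results of that scaling depend largely on high Fe replicate 2. Its control mean (log2) was 10.265 on 230A and 11.981 on 230B, above 9.226 to 9.517 and 11.146 to 11.403 on the other arrays. Against 9 probe sets on 230A, the alternatives gave 15 at adjusted p 0.1, 4 with a replicate block (all 4 shared with the 9), 14 with the RNA quality block (9 shared) and 33 with the hybridization controls (8 shared), which moved the median log2 difference of all probe sets from -0.015 to 0.342. Leaving out 1 array gave 5 (without low Fe replicate 2) to 21 (without low Fe replicate 1). Deviations of arrays with the same number correlated at -0.356, -0.149 and -0.252 on 230A and at -0.265, -0.099 and -0.166 on 230B. These values give no sign that the numbers pair the samples. They cannot exclude it, since samples with the same number lie in opposite RNA quality sets. With the replicate block the adjusted p was 0.152 for Hmox1, 0.210 for P4ha1 and 0.128 for Ugt2b35, while Slc11a2, Cybrd1 and Tfrc passed. These 3 genes passed under each alternative run on 230A. On 230B the count was 0 under each alternative but the hybridization controls, which gave 4 and moved the median from -0.0408 to 0.143. The count of 9 lists on 230A became 0 with an estimated correlation and 2 by fry. It was 0 on 230B, where 6 lists were tested. On 230A it ran from 6 to 11 when 1 array was left out. Signs were followed over the settings for the genes named here, apart from Apoa4, Gata4 and further probe sets of a gene. They reversed with 1 array left out for Heph (-0.0013 to 0.1742), Slc39a14 (-0.0215 to 0.1629), Slc39a8 (-0.0828 to 0.0202), Ldha (-0.2278 to 0.0893) and Eno1 (-0.1495 to 0.0624). On 230B they did so for Mylk (-0.3033 to 0.4669), Des (-0.3141 to 0.8504) and Synm (-0.1911 to 0.0555). With the hybridization controls they reversed for Acadm (0.0413), Ldha (0.3028), Eno1 (0.3142), Cox4i1 (0.13) and Slc39a8 (0.3453), all under the median of 0.357 over all tested genes there, and for Synm on 230B (0.0935). With a common median they reversed for Eno1 (0.0081), Slc39a8 (0.0423) and Synm on 230B (0.0376), with quantile normalization for Ldha (0.051) and Eno1 (0.0418), and with the RNA quality block for Ldha (0.0429) and Eno1 (0.0157). With the mean of a gene's probe sets they reversed for Epas1 (-0.0488) and Slc39a6 (-0.1929), and on the other array type for Itga6 (-0.3385), Fnbp4 (0.2391), Slc39a14 (-0.2857), Synm (0.1251) and Atp2b1 (0.5367 for the brightest of 3 probe sets on 230B, -0.70 for the dimmest). None of these genes passed in either setting. Apoa4 and Gata4 also changed sign without 1 array (-0.3545 to 0.0065 and -0.1222 to 0.1002). Apoa4 lay above 0 with the hybridization controls. With the mean of a gene's probe sets, Gata4 (0.016 and -0.7968) and RT1-Ba on 230A (-0.4155 and 0.4179) reversed too. On 230B Atp2b1 did so as well (0.5367, 0.1592 and -0.6986). RT1-Ba and Atp2b1 reversed only to near 0. Apart from the change with an estimated correlation, which uses the 4 residual degrees of freedom and each list's own correlation, the cause was not tested. Signal over background limits the dim genes, whose folds are understated, and the 40% of probe sets with the lowest signal were not tested.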

Other observations

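The tests of array scaling, of proximal gut, of correlated genes within lists, of the 5'/3' ratios and of the cytochrome P450 genes, and the scaling to the hybridization controls, were chosen only after the results were seen. Enzymes of drug and steroid metabolism beside the Ugt2b genes, named here after their values were seen, did not pass over all probe sets. Cyp1a1, which oxidizes polycyclic aromatic compounds, gave the log2 difference furthest from 0 among them, -1.75 ± 0.48 (SE, adjusted p = 0.523). It was among the 33 probe sets past the threshold after scaling to the hybridization controls, at -1.41 (limma adjusted p = 0.0298). All 33 lay at least 1.3786 from 0, and Cyp1a1 passed though its difference had shrunk. Passing there therefore adds no support for its fall. Cyp27a1, a sterol hydroxylase, gave -0.51 ± 0.14, and Cyp4f5, a fatty acid hydroxylase, gave -0.46 ± 0.19. The sulfotransferases Sult1b1 and Sult6b2 gave -0.47 ± 0.19 and -0.43 ± 0.13, and the glutathione transferase Gstm3 gave 0.55 ± 0.20.

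Of the 24 tested genes whose symbols start with Cyp, the cytochrome P450 enzymes, 19 lay below 0 on 230A, with a median of -0.17. The hypothesis of a joint fall was tested by camera against 99 families of at least 8 genes that share the start of their symbols. The adjusted p was 0.0593, and 0.984 with an estimated correlation, so the hypothesis was not supported. The family's median was -0.10 with a common median of the arrays and -0.13 with quantile normalization. It was 0.19 after scaling to the hybridization controls, where all tested genes had a median of 0.36.

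The rise of Slc11a2, Cybrd1 and Tfrc in low Fe was set against 3 technical explanations. Array scaling was argued against, since the smallest log2 difference of the 3 genes over 3 other scalings (a common median, quantile normalization and the hybridization controls) was 2.2405. A single aberrant array was argued against by the highest adjusted p of the 3 genes without any 1 array, 0.0276. More proximal gut in the low Fe scrapes cannot be told apart from the iron groups: the 4 tested duodenal genes had a median log2 difference of -0.0731, but bright ones such as Apoa4 and Gata4 (means of 13142 and 2400 in high Fe) would hide a small share of duodenum. The 3 genes differed between the iron groups that the design names, but iron as the cause was not tested apart from other differences between these groups.

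With 3 samples against 3 there are 10 splits of the 6 samples, too few for a share under 0.05. On 230A 2 of the 10 splits gave at least the real count of 9 probe sets, the highest other being 172, and 1 of 10 gave at least the real count of 9 lists, the highest other being 7. On 230B the real count was 0, which each of the 10 splits reaches by construction, so that count says nothing, and the highest other was 65.

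The split that set high Fe replicate 1 and low Fe replicates 2 and 3 against the other 3 samples called 172 probe sets on 230A, several times the 9 of the iron groups, and 65 on 230B, where the iron groups gave 0, which points to a structure of the samples. Overall array brightness was argued against as the whole cause, in a test fixed after the split was seen and before its own result: after quantile normalization that split called 137 probe sets on 230A. RNA or target with less 5' sequence in 3 of the 6 samples may contribute, since the sets did not overlap in 4 of 4 ratios, those of GAPDH and beta-actin on either array type. Both types measured the same 6 samples, so the 4 ratios are not independent. For GAPDH on 230B the sets parted narrowly, at 0.873 in low Fe replicate 3 against 0.877 in low Fe replicate 1. The means of the hybridization controls also parted the sets on both types. Differences between the rats themselves stay open as untested, and with these sets as a block the iron groups gave 14 probe sets on 230A, with the 9 among them.

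Each of the 9 lists past the threshold on 230A was set against correlated genes within lists as an explanation. For hypoxia targets and iron handling the correlation that would end the call exceeded the estimated one plus 2 jackknife SE by at least 0.0689. The former was found at preset values, while the estimates rest on 4 residual degrees of freedom. Both estimates (-0.02 and -0.0002) lay under the preset 0.01 at which the lists passed, and the calls would end at 0.218 and 0.15. These values argue against correlated genes as the explanation for these lists, as far as estimates from so few samples can. Neither list passed by camera with an estimated correlation (adjusted p = 0.0801 and 0.129), where the test uses the 4 residual degrees of freedom. For the brush border and cell cycle lists correlated genes may account for the call. Their estimated correlation less 2 jackknife SE exceeded the correlation that would end the call by at least 0.0991. For the other 5 the jackknife range spanned it, so the explanation stays open. For the smooth muscle list more muscle in the low Fe scrapes is a hypothesis that its test left open: the heterogeneity p of the 7 log2 differences was 0.105, and the list's median deviation was -0.409, -0.203 and -0.035 in the high Fe samples and 0.089, 0.331 and 0.367 in the low Fe samples. The markers with the highest signals were Mylk (2754 in high Fe, 3711 in low Fe) and Acta2 (523 and 657), though signals of different probe sets do not rank abundance, 0 of the list's 13 genes stand in another list, and on 230B the log2 differences were 0.41 for Des, 0.09 for Mylk and -0.09 for Synm, synemin, each of which changed sign without 1 array. For this list too, iron as the cause was not tested apart from other differences between the groups.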
